A study of Mus musculus with 50 samples.

How the data were processed

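RNA-seq was made from 50 mouse liver samples in 10 groups of 5. Per the labels, FVB mice received a hydrodynamic tail vein injection of plasmids for Sleeping Beauty transposition, which places the injected coding sequences in the genome of hepatocytes. One plasmid carried a form of β-catenin (gene Ctnnb1) and another carried YAP S127A, a form of the YAP protein (gene Yap1) that escapes an inhibitory phosphorylation. The label of every tumour also lists xloc, whose meaning is not given here. The 9 tumour groups differ in the β-catenin form and are named by it: Del20-32, Del36-53 and Del90 (deletions near the N-terminus), S33A, S33Y and S45A (substitutions near the N-terminus), K335I and N387K (substitutions further along the protein) and WT (unmutated β-catenin). The tenth group is normal liver from mice without injection. The labels give 28 males and 22 females. Replicate numbers were given here in accession order within a group, so they only name a library and pair nothing. Each sample has its own identifier in the labels and every group holds both sexes, so the tumours of a group came from more than 1 mouse. That all 5 came from separate mice is not stated there, so the p-values may measure in part a spread between tumours of the same mouse.

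Per the labels' protocols and the series' design text, RNA was purified on columns with DNase digestion, mRNA was captured with oligo(dT), directional libraries were made with an NEBNext Ultra kit and sequenced on an Illumina NovaSeq instrument. The flow cell and lanes named in some column names were not checked against this instrument. Whether all libraries were run on it therefore stays open. The build GRCm38.p6 is named in the submitters' processing notes. The file headers call the reads paired and trimmed. The deposited name carries the label CLC. Beyond it, the aligner and the counting program are not given in the sources used here. Whether counting used strand is not given either, so values of genes with near-identical copies (such as the Mup genes and several Cyp2, Cyp3 and Hba families) and of overlapping or antisense genes are uncertain.

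The authors deposited a single table with 36333 genes. Its per-library values are a signal on a scale-adjusted CPM scale (counts, rescaled to the library total and a scale factor), per the file headers, with column sums from 0.825 to 1.558 M. The table also holds the authors' own log2 fold changes and FDR p-values for 45 comparisons of 2 groups, per the file headers, which are used here only as counts of genes under 0.05 and are named as the authors' deposited table. Each library's values are whole multiples of the value of 1 read: 100% of the non-zero values came out whole within 0.01 in every library, and this gives the library totals. They ran from 16.5 to 36.2 M reads. The deposited scale factors ran from 0.642 to 1.21 and lay within 0.979 to 1.02 times the TMM factors computed from the recovered reads (r = 0.998 across the 50 libraries). The file lists 10362 genes at 0 in every library, and 1 symbol occurs more than once. No per-sample column was left unused.

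The deposited column names differ in form. For 25 libraries (normal liver, Del20-32, Del90, S33A and S45A) they name a flow cell and lane, and for the other 25 (Del36-53, K335I, N387K, S33Y and WT) they do not. Totals were 16.55 to 20.16 M reads (median 18.47) in the first set and 20.24 to 36.21 M (median 24.6) in the second. No group has libraries in both sets. A difference between groups of different sets therefore cannot be told apart from a difference between the sets, and for comparisons that can be made inside 1 set the values there are given for part of the genes and lists, with counts of the genes that kept their call. For a pair of groups of the same set, such a fit keeps the same libraries of that pair. Its fold changes are close by construction, and only the sex term, variance and filter differ.

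The tests had been planned for raw counts, with edgeR's quasi-likelihood test first. Because the table holds scale-adjusted CPM, the test used throughout was limma (empirical Bayes with a mean-variance trend) on log2(value + 1), and edgeR was run on the recovered reads as an alternative chosen after seeing the data. A fold change is on the log2(value + 1) scale, which understates changes of genes near 0. Genes with at least 1 CPM in at least 5 libraries were tested: 14280 with the normal livers and 14129 among the 45 tumours. P-values were adjusted by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. All comparisons with normal liver and of the sexes came from 1 fit to the 50 libraries, with separate sex terms in tumours and in normal liver. All comparisons among tumours came from 1 fit to the 45 tumours with a sex term. The adjusted p-values in the report are from these limma fits unless another tool is named. Values in the form mean ± SD are CPM over libraries, with n = 5 per group unless stated.

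The comparisons were the tumour average (the mean of the 9 group coefficients) and each tumour group against normal liver, males against females in each tissue and the difference of these differences, any difference among the 9 tumour groups (an F test on 8 degrees of freedom), each of the 8 mutants against WT, the 3 N-terminal deletions against the 3 N-terminal substitutions, K335I and N387K against the 6 N-terminal mutants, S33Y against S33A and N387K against K335I. Gene lists, 33 in number, were fixed with the design: Wnt feedback and target, pericentral, periportal, YAP/TEAD target, oncofetal and imprinted, cholangiocyte and progenitor, mature hepatocyte, cell cycle, glycolysis, fatty acid oxidation, respiratory chain, ribosomal protein, NRF2 target, cholesterol synthesis, lipogenesis, urea cycle, bile acid, male-biased, female-biased, macrophage and Kupffer cell, lymphocyte, neutrophil, endothelial, stellate cell and fibroblast, erythroid and blood, adipocyte with muscle and pancreas, interferon-stimulated, antigen presentation, acute phase, p53 target, unfolded protein response, hypoxia and epithelial-mesenchymal genes. Each list with at least 3 tested members was compared with the other genes by camera with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data. Of the 333 list calls over all comparisons, 7 held with an estimated correlation, all in the comparisons of the sexes.

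The rule for named genes was fixed with the design. It takes Ctnnb1 and Yap1 in every comparison. In the tumour average and the pooled classes it takes the 6 largest rises and 6 largest falls, and in the other comparisons of 2 groups the 3 largest of each, among called genes with a mean of at least 10 CPM on the higher side and a symbol that is not a predicted or clone name. In the test of any difference it takes the 12 smallest p-values. From each list it takes up to 4 called members with the smallest adjusted p or, where none was called, up to 2 with the highest mean, and all members of the Wnt, pericentral, YAP/TEAD and oncofetal lists may be named. Not every gene the rule allows is named, and 1 gene in the test of any difference is not reported here.

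Alternatives fixed before the data were examined were RLE size factors, no filter on low values, DESeq2 on the recovered reads, no sex term, a term for the number series of the sample identifiers, a fit of only the 2 groups compared, leaving out each library in turn (95 fits), estimated correlations and fry for the lists, and leaving out the 17 genes that take over 1 percent of the reads of any library. Chosen after seeing the data were edgeR on the recovered reads, a pseudocount of 0.25, values with no scale factor, an exchange of the sex labels of S33Y libraries 1 and 2, leaving out K335I 3, S33Y 1 and S33Y 2 together, fits and list tests within 1 sequencing set, list tests without K335I 3, and K335I and N387K against each N-terminal group singly. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

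The fits named in this paragraph, and camera for S33Y against WT, were tested on simulated data first. The other comparisons, fry and the correlations were not simulated. In reads simulated for S33Y against WT, limma recovered 70 of 100 genes changed 2-fold and 90 of 100 changed 4-fold, with 5.88% of its calls false. A fit of only these 2 groups recovered 47 and 87. For the tumour average against normal liver limma recovered 83 and 98 (6.22% false), for the sexes in tumours 95 and 97 (5.42% false), and for any difference among tumours 64 and 85 (5.7% false). For S33Y against WT edgeR recovered 71 and 91 (3.57% false) and DESeq2 75 and 92 (9.24% false). The DESeq2 likelihood ratio test for any difference made 25.9% false calls there. Of 100 pairs of libraries within groups, none matched within sampling noise (the smallest chi-square per degree of freedom was 20.0), so no library was treated as a repeat of another. This does not show that samples came from separate mice.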

Results

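Liver tumours of mice that had received a form of β-catenin together with YAP S127A were profiled by RNA-seq with 5 tumours for each of 9 β-catenin forms, beside 5 normal livers from mice without injection. β-catenin carries the canonical Wnt signal to TCF/LEF transcription factors and YAP is the transcriptional coactivator held in check by the Hippo pathway. The series asks how the form of β-catenin bears on the tumour that results. Libraries held 16.5 to 36.2 M reads. Normal liver, Del20-32, Del90, S33A and S45A libraries form one sequencing set (a flow cell is named in the deposited column) and Del36-53, K335I, N387K, S33Y and WT libraries another, and no group has libraries in both. The first principal component of the tumours took 24.3% of their variance and the second 11.9%, of which the sequencing set accounted for 0.682% and 60.3%.

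**Figure D1:**
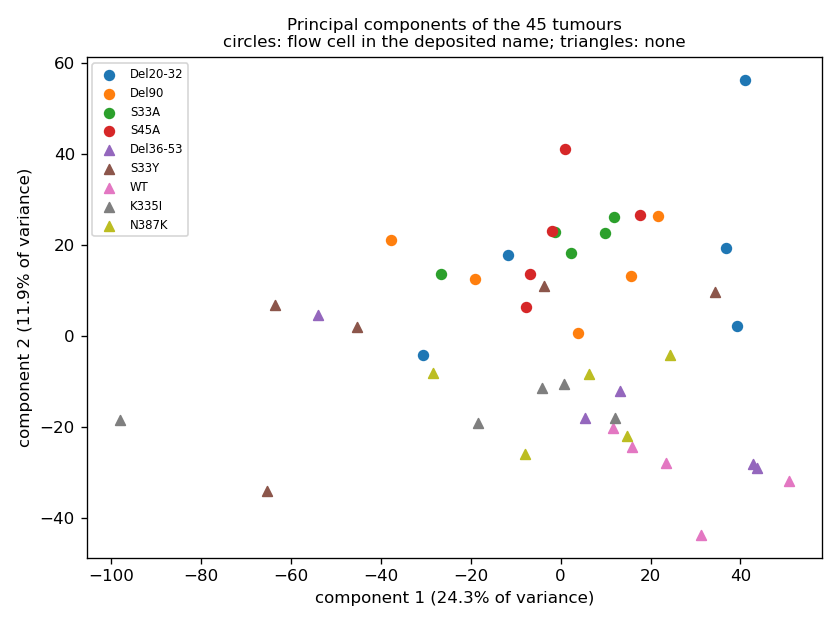
First and second principal components of the 45 tumours (24.3% and 11.9% of the variance), with 1 point per library. Colour marks the tumour group and symbol the sequencing set (circles, flow cell named in the deposited column, and triangles, none named). The sets separate mostly along the second component.

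Transcripts of both plasmid genes were raised in the tumours. Ctnnb1 averaged 1389 ± 1021 CPM over the 45 tumours against 372 ± 33.2 CPM in normal liver (log2 fold change 1.65, SE 0.21, adjusted p = 1.42e-08), and Yap1 averaged 3222 ± 1499 CPM against 112 ± 12.9 CPM (4.67, SE 0.34, 7.18e-15). Within the first sequencing set the log2 fold changes were 1.28 and 4.98. Each gene has 1 value per library, so transcripts of a plasmid are not separated from those of the mouse gene. WT tumours had the highest Ctnnb1 mean, 3498 ± 1817 CPM, and S33A tumours the lowest, 653 ± 125 CPM. Yap1 group means ran from 1715 ± 951 CPM in K335I tumours to 4166 ± 2316 CPM in Del36-53 tumours. K335I 3 held 282 CPM of Yap1.

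**Figure D2:**
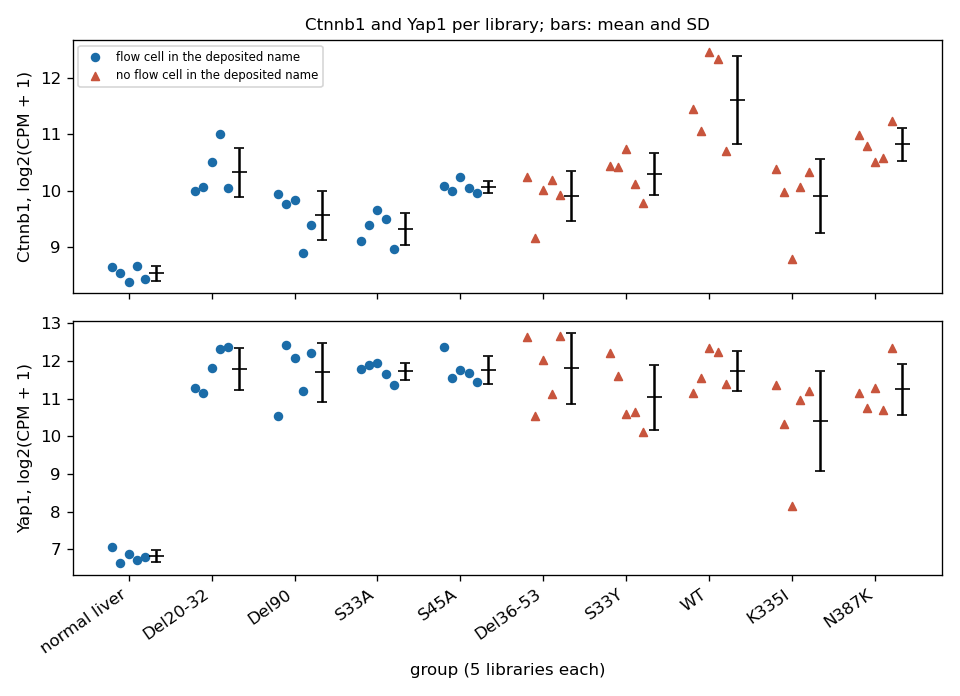
Ctnnb1 and Yap1 in each library, as log2(CPM + 1), for normal liver and the 9 tumour groups, with 5 points per group and the mean and SD as a bar beside them (blue circles, flow cell named; red triangles, none named). WT tumours have the highest mean of Ctnnb1 (3498 CPM), and Yap1 is above the normal livers (mean 112 CPM) in every tumour.

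Against normal liver the tumours as a whole gained Wnt, YAP and fetal transcripts. Among Wnt target genes, Tnfrsf19 (log2 fold change 4.0), the negative feedback gene Axin2 (3.31, SE 0.27), the stem cell receptor Lgr5 (2.66) and the transcription factor Tbx3 (1.43) rose. Axin2 was at 11 ± 1.39 CPM in normal liver and between 79.8 ± 19.1 CPM (K335I) and 215 ± 82.6 CPM (S33Y) in the tumour groups. Of 17 tested members of the Wnt list 13 rose and 1 fell (14 when adjusted over the list alone, camera adjusted p = 0.00039, but adjusted p = 0.354 with an estimated correlation). The one that fell was Notum, a secreted Wnt inhibitor (-1.04, adjusted p = 0.0212). Its call ended within the first sequencing set (-0.29, 0.383), with no scale factor (-0.49, 0.263) and without 2 libraries, at most 0.0977 without normal liver 1. YAP/TEAD targets rose in 15 of 23 cases and fell in 1 (16 over the list alone, camera 0.00039, adjusted p = 0.354 with an estimated correlation): Ankrd1 (6.36, from 0.361 to 142 ± 79.7 CPM), Myof (4.04), Ajuba (3.75) and the matricellular genes Ctgf (3.56) and Cyr61 (2.48). Oncofetal and imprinted genes rose in 13 of 18 cases and fell in 1 (14 over the list alone, camera 0.0102, adjusted p = 0.369 with an estimated correlation), with the membrane proteoglycan Gpc3 at 6.15, Igf2bp1 at 4.71 and Epcam at 4.12. The imprinted RNA H19, the fetal growth factor Igf2 and α-fetoprotein (Afp) rose by 5.83, 3.70 and 3.60, and within the first sequencing set by 3.85, 1.71 and 2.96.

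The tumours also gained proliferation and progenitor transcripts. Of 25 cell cycle genes 24 rose (24 over the list alone, camera 4.9e-10, adjusted p = 0.354 with an estimated correlation), among them Mki67 (3.75) and Ccna2 (3.41). Of 15 cholangiocyte and progenitor genes 12 rose and none fell (12 over the list alone, camera 0.000273, adjusted p = 0.354 with an estimated correlation), with the biliary factors Sox4 (4.60) and Sox9 (2.62) and the integrin Itgb4 (4.25). Interferon-stimulated genes rose in 12 of 15 cases (12, 0.000461, adjusted p = 0.364 with an estimated correlation), led by Ifit2 (3.60). Among p53 targets 10 of 14 rose and 1 fell (11 over the list alone, 0.00348, adjusted p = 0.354 with an estimated correlation), including the cell cycle inhibitor Cdkn1a (5.04) and Phlda3 (4.07). Ribosomal protein genes rose in 52 of 77 cases and fell in 2 (54, 0.00181, adjusted p = 0.882 with an estimated correlation), by smaller amounts such as 0.77 for Rplp0. The 6 largest rises of all were in Fgfbp1 (6.75, SE 0.57, 152 ± 85.8 against 0.131 CPM), Scube3 (6.71), Ankrd1 (6.36), the growth factor binding protein Igfbp1 (6.31, 480 ± 420 against 3.58 CPM), the surfactant protein Sftpd (6.27) and the iron-scavenging lipocalin Lcn2 (6.16, 340 ± 141 against 4.87 CPM).

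Transcripts of hepatocyte metabolism fell. The respiratory chain list fell in 22 of 22 cases (22 over the list alone, camera 4.66e-12, adjusted p = 0.354 with an estimated correlation), for example Atp5a1 by 1.17 and Ndufv1 by 1.03 on the log2 scale. Fatty acid oxidation genes fell in 18 of 19 cases (18, 4.9e-10, 0.354 with an estimated correlation), with Acaa1b at -2.70, Ehhadh at -2.51 and Cpt2, which acts at carnitine-dependent import into mitochondria, at -1.72. Mature hepatocyte genes fell in 19 of 22 cases (19, 4.69e-08, adjusted p = 0.354 with an estimated correlation), including the thyroid hormone carrier Ttr, from 7631 to 1224 CPM. Lipogenesis genes fell in 15 of 16 cases (15, 7.99e-06), with Thrsp at -5.69 and the regulator Srebf1 at -1.68. All 8 urea cycle genes fell (8, 0.000407), among them Otc at -4.05. Bile acid genes fell in 14 of 17 cases (14, 0.000179), with the nuclear receptor Nr0b2 at -2.58, and male-biased liver genes in 11 of 15 (11, 0.000179), with Cyp2u1 at -4.08. These last 4 lists had an adjusted p = 0.354 with an estimated correlation. Periportal genes fell in 18 of 20 cases and rose in 1 (19, 6.57e-05, adjusted p = 0.369 with an estimated correlation), with the amino acid catabolic genes Hal at -5.13 and Gls2 at -5.17. The 6 largest falls were in the major urinary protein genes Mup2 (-7.85), Mup9, Mup19, Mup10, Mup7 and Mup1 (-7.18), near-identical copies whose separate values are uncertain.

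Pericentral hepatocyte genes, several of which depend on Wnt signalling in normal liver, moved both ways: 3 of 20 rose and 7 fell (10 over the list alone, camera 0.362, adjusted p = 0.882 with an estimated correlation). The list's median was -0.14, and 0.42 with no scale factor, where 8 rose and 6 fell. The vasopressin receptor Avpr1a (2.12), Slc13a3 (2.05) and the aryl hydrocarbon receptor Ahr (1.72) rose, while the xenobiotic genes Cyp2c29 (-5.87) and Cyp1a2 (-2.63) and their regulator Nr1i3 (-4.35) fell. Glul (glutamine synthetase) was at 0.92 (adjusted p = 0.066) and the glutamate transporter Slc1a2 at 0.52 (0.579), and neither passed.

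Of the remaining lists none was called by camera. Macrophage and Kupffer cell markers rose in 8 of 16 cases and fell in 4 (camera 0.441), with Trem2 at 2.99. Stellate cell and fibroblast markers rose in 7 of 16 and fell in 5 (0.998), with Timp1 at 2.27 and Col1a1 at 2.20 but Lrat at -2.54. Endothelial markers fell in 7 of 14 and rose in 2 (0.0559), with the sinusoidal genes Dnase1l3 at -3.09 and Oit3 at -2.66 and with Cd34 at 2.13. Epithelial-mesenchymal genes rose in 8 of 15 and fell in 2 (0.0562), with S100a6 at 3.97. Rises and falls were 8 and 5 of 17 for glycolysis (0.998), 4 and 5 of 20 for NRF2 targets (0.449), 1 and 7 of 18 for cholesterol synthesis (0.0562), 1 and 9 of 16 for female-biased genes (0.0562), 2 and 3 of 12 for lymphocytes (0.362), 3 and 0 of 6 for neutrophils (0.389), 2 and 0 of 8 for erythroid and blood genes (0.68), 1 and 1 of 5 for adipocyte, muscle and pancreas genes (0.998), 5 and 2 of 14 for antigen presentation (0.837), 3 and 2 of 16 for acute phase genes (0.949), 5 and 2 of 15 for the unfolded protein response (0.611) and 3 and 3 of 13 for hypoxia genes (0.864). With no scale factor the medians of NRF2 and cholesterol synthesis genes turned from -0.03 to 0.53 and from -0.47 to 0.08.

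In total 5167 of 14280 genes rose and 4090 fell in the tumour average (limma). Dropping the scale factor shifted the median of all genes by 0.52 and raised the share of rises among calls from 55.8% to 84.1%, so the balance of rises and falls depends on the scaling. Within the first sequencing set 9419 genes were called, and of 176 genes named by the rule 174 kept their direction and their side of the threshold there, Notum and Cdkn1c (0.25, adjusted p = 0.18) being the exceptions. In that set Axin2 was at 3.52, Lgr5 at 2.96, Ankrd1 at 6.88, Gpc3 at 6.27, Fgfbp1 at 7.28, Sox9 at 2.66, Mki67 at 3.76, Hal at -5.14, Otc at -4.49, Thrsp at -5.35, Atp5a1 at -1.28 and Mup2 at -7.93. The female-biased list was called downward in that set (11 of 15 fell, camera 0.0441, adjusted p = 0.728 with an estimated correlation).

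Each β-catenin form gave tumours that as a group lay far from normal liver. Single tumours lay nearer: K335I 3 lay 73.7% of the way from the mean tumour to the mean normal liver. S33Y 3, S33Y 5 and Del36-53 2 lay at 42.2, 38.1 and 36.1%, and all other tumours at most at 26.0%. The Wnt, YAP/TEAD, cholangiocyte and progenitor, cell cycle, interferon and p53 lists were called upward, and the periportal, mature hepatocyte, fatty acid oxidation, respiratory chain, lipogenesis, urea cycle, bile acid and male-biased lists downward, in all 9 groups by camera, and in none with an estimated correlation. Cell cycle genes rose in 22 to 24 of 25 cases per group and Wnt genes in 9 to 14 of 17. The oncofetal list was called upward in N387K (15 of 18 rose), Del36-53 (13), WT (12), Del90 (10) and K335I (10), with adjusted p = 0.361, 0.320, 0.468, 0.470 and 0.439 in that order with an estimated correlation, and not in S33A (8), S45A (8), Del20-32 (6) or S33Y (6). Pericentral genes were called downward in Del36-53 (3 rose, 10 fell, adjusted p = 0.496 with an estimated correlation) and N387K (3 and 9, adjusted p = 0.502 with an estimated correlation), while in S33Y 8 of 20 rose and 2 fell. These differences between groups are tested further on, among the tumours. Ctnnb1 and Yap1 were called in every group, with log2 fold changes from 0.78 (S33A) to 3.05 (WT) for Ctnnb1 and from 3.70 (K335I) to 5.02 (Del36-53, S33A) for Yap1.

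Rises and falls against normal liver (limma) were 4315 and 3475 for Del20-32, 4766 and 3704 for Del36-53, 4128 and 3366 for Del90, 3652 and 2810 for K335I, 4490 and 3468 for N387K, 4433 and 3755 for S33A, 3658 and 3014 for S33Y, 4223 and 3573 for S45A and 4858 and 3701 for WT. The shares of rises, 54.1% (S33A) to 56.8% (WT), became 80.5% (WT) to 88.3% (Del90) with no scale factor, which moved the median of all genes by 0.38 (S33Y) to 0.63 (S33A). Normal liver shares its sequencing set with Del20-32, Del90, S33A and S45A. In fits within that set 155 of 156, 158 of 158, 166 of 166 and 161 of 161 named genes kept their calls in these 4 groups. These fits hold the same libraries of the groups compared, so close values are given by construction. There Lcn2 was at 5.96 to 6.37, Ankrd1 at 6.69 to 7.15 and Yap1 at 4.90 to 5.09. The other 5 groups have no normal liver in their set, and against that of the first set Lcn2 was at 5.50 (S33Y) to 6.38 (K335I), Ankrd1 at 3.89 (S33Y) to 6.97 (WT) and Yap1 at 3.70 (K335I) to 5.02 (Del36-53). How much a set difference adds to the value of a single gene in these 5 groups is not separated.

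Liver genes known to differ between the sexes did so in normal liver and in tumours. In normal liver (2 males, 3 females) the male-biased enzymes Cyp4a12a (log2 fold change 8.49, 583 against 0.698 CPM), Cyp2d9 (7.90) and Hsd3b5 (7.22) were higher in males, and Cyp2b13 (-8.47), Hao2 (-7.53) and the transcription factor Cux2 (-5.09) were higher in females. Of the male-biased list 12 of 15 were higher and none lower in males (14 over the list alone, camera 5.51e-35, adjusted p = 0.00014 with an estimated correlation), and of the female-biased list 14 of 16 were lower (15, 6.37e-31, adjusted p = 0.00105 with an estimated correlation). In tumours Mup20 (3.95, 476 against 29.1 CPM), Cyp4a12a (2.92) and Cyp7b1 (1.91) were higher in males and Cyp2a4 (-3.12), Hao2 (-2.08) and Cux2 (-1.81) in females. There 8 of 15 male-biased genes were higher in males (12 over the list alone, 8.61e-17, adjusted p = 0.017 with an estimated correlation) and 9 of 16 female-biased genes lower (15, 2.92e-19, adjusted p = 0.017 with an estimated correlation). Tested as the difference of the differences, 6 of 15 male-biased genes lay lower (11 over the list alone, 7.85e-27, adjusted p = 0.00115 with an estimated correlation) and 4 of 16 female-biased genes higher (14, 5.82e-22, adjusted p = 0.0091 with an estimated correlation). Antigen presentation genes lay higher there as a list with none called singly (10 over the list alone, 6.55e-13, adjusted p = 0.0176 with an estimated correlation). Ctnnb1 and Yap1 did not pass between the sexes in normal liver (0.21, adjusted p = 0.954 and 0.13, 0.996) or tumours (-0.02, 0.963 and -0.39, 0.38).

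Between males and females, 124 genes were higher and 122 lower in normal liver, 148 higher and 80 lower in tumours, and 52 and 41 for the difference of the differences (limma), a count that 22 of 100 splits of the libraries reached. These splits shuffle sex within groups, and some may keep the real sexes of normal liver. The share of genes higher in males went from 50.4% to 34.4% in normal liver with no scale factor (median shift -0.18), and from 55.9% to 67.1% for the difference of the differences (0.16). The count in normal liver was 61 without normal liver 4, 114 without 1, 128 without 5 and 133 without 3, and that of the difference of the differences was 15, 44, 45 and 36 in that order. The count in tumours was 108 without Del20-32 2, 114 without S45A 1, 124 without N387K 4, 132 without S33A 1, 133 without K335I 5, 364 without Del36-53 2 and 3.9e+02 without S33Y 2. S33Y 1, labelled female, had 0.312 CPM of Xist, the female-specific RNA of the inactive X chromosome, and S33Y 2, labelled male, had 610 CPM.

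Among the 9 tumour groups 4792 of 14129 genes differed (33.9%, limma F test). Among the smallest p-values were those of the histone gene Hist1h2ao (adjusted p = 9.89e-21), Bahcc1 (1.6e-11), AW549542, the adrenergic receptor Adra1d (8.92e-09), the fatty acid transporter Cd36 (9.64e-08), Tbx3 (1.33e-07), Diaph1, coagulation factor F5, Zfp729b, the complement receptor Cr2 and Snhg18 (2.85e-07). Of the lists, the groups differed in 11 of 17 Wnt genes (12 over the list alone), 13 of 20 pericentral (13), 11 of 15 cholangiocyte and progenitor (13), 12 of 19 fatty acid oxidation (14), 8 of 18 oncofetal (8), 8 of 23 YAP/TEAD (8) and 4 of 25 cell cycle genes (0). Sox9 (3.47e-07), Aldh1a1 (2.68e-06), Glul (1.43e-05), Notum (2.35e-05), Nkd1 (4.73e-05), Peg3 (5.75e-05), Slc1a2 (7.38e-05) and H19 (0.000111) were among them. Ctnnb1 differed (1.15e-05) and Yap1 did not pass (0.114). Without K335I 3, S33Y 1 and S33Y 2 Yap1 passed (0.0442), in a fit whose remaining S33Y tumours are those nearest to normal liver. Within the first sequencing set 18 genes differed among its 4 tumour groups, none of them named here, with Ctnnb1 at 0.114, Glul at 0.416 and Sox9 at 0.993. Within the second set 734 differed among 5 groups. Of 134 called genes the rule allows, none passed again within the first set and 51 did within the second. Of the genes named here Yap1 (0.303) and Zfp729b (0.442) did not pass in the second set and Hist1h2ao was too low to be tested. Hist1h2ao was at 10.7 to 146 CPM in tumours of the first set, at most 0.684 CPM in those of the second and 1.32 to 7.29 CPM in normal liver.

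**Figure D3:**
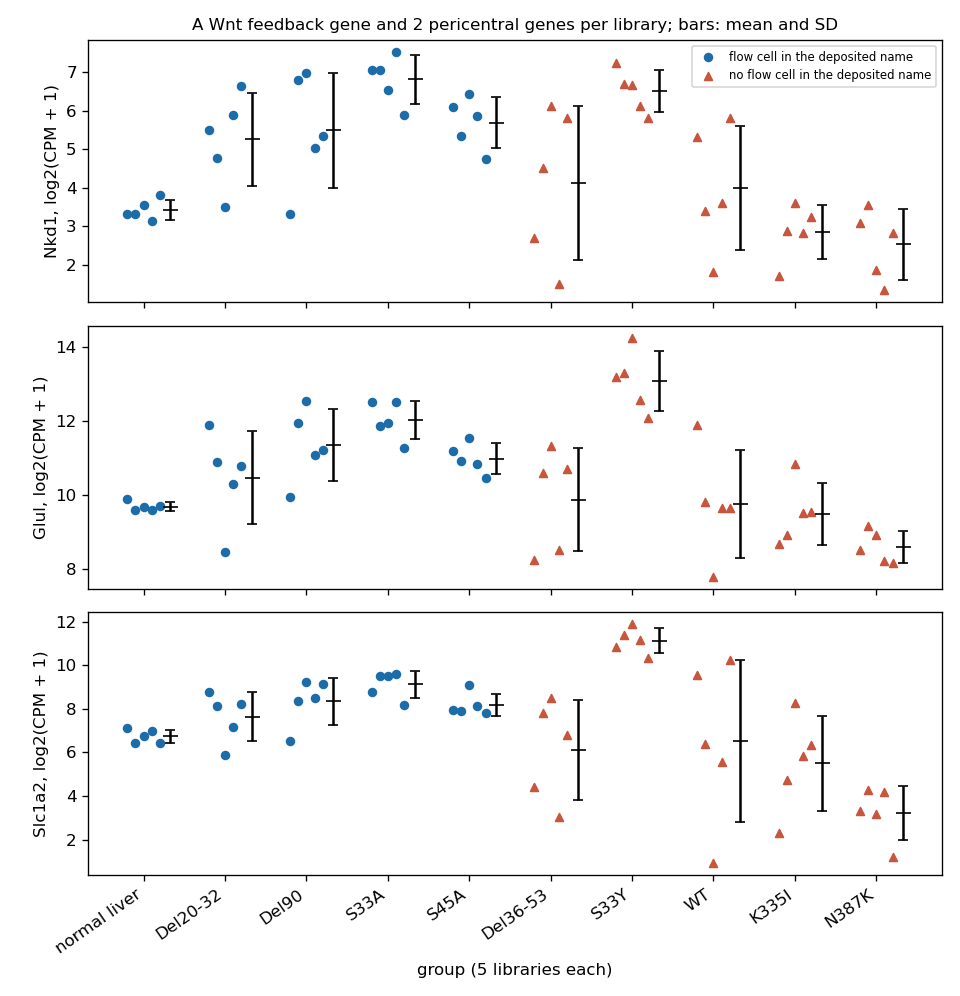
Nkd1, Glul and Slc1a2 in each library, as log2(CPM + 1), with 5 points per group and the mean and SD as a bar beside them (blue circles, flow cell named; red triangles, none named). S33Y tumours have the highest means of Glul (9899 CPM) and Slc1a2 (2385 CPM), and N387K tumours the lowest of all 3 genes (403, 10.7 and 5.68 CPM for Glul, Slc1a2 and Nkd1).

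Of the groups of one sequencing set with WT, S33Y differed from it in the most genes, with 13 of 20 pericentral and 15 of 19 fatty acid oxidation genes higher and 6 of 18 oncofetal genes lower. On the line from the mean tumour to the mean normal liver, S33Y 3, 4 and 5 lay at 42.2, 22.8 and 38.1%, S33Y 1 and 2 at -21.1 and -5.17%, and the 5 WT tumours at -25.5 to -4.39%. Glul was at 9899 ± 5827 against 1311 ± 1434 CPM (log2 fold change 3.36, SE 0.61, adjusted p = 0.000231), where the WT mean was 681 ± 310 CPM (n = 4) without WT 1. Tbx3 was at 316 ± 113 against 69.7 ± 47.5 CPM (2.34, SE 0.29, 5.5e-07) and Ces1f, a carboxylesterase, at 225 ± 93.1 against 2.52 ± 3.04 CPM (6.47, 2.43e-05). Sox9 was at 3.68 ± 1.88 against 88.3 ± 13.3 CPM (-4.38, SE 0.49, 6.99e-08), the growth factor binding protein Igfbp2 at 67.2 against 1777 CPM (-4.90, 2.26e-07), Bex1 at 2.45 against 195 CPM (-5.70, 3.78e-05) and H19 at 11 ± 10 against 2856 ± 3037 CPM (-7.17, SE 1.42, 0.000609). Within the second sequencing set these log2 fold changes were 3.40, 2.37, 6.41, -4.34, -4.90, -5.75 and -7.40, and all 7 passed. The S33Y and WT libraries are the same in both fits, so close fold changes are given by construction. Ctnnb1 was lower in S33Y (-1.31, 0.00192, and -1.28, 0.0214 within the set), and Yap1 did not pass (-0.79, 0.236) but passed without K335I 3, S33Y 1 and S33Y 2 (-1.39, 0.0135). That last fit keeps only S33Y 3, 4 and 5, the S33Y tumours nearest to normal liver.

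By list, 13 of 20 pericentral genes were higher in S33Y than in WT and none lower (13 over the list alone, camera 2.84e-08, adjusted p = 0.401 with an estimated correlation), with Aldh1a1 at 1.34, Cyp1a2 at 3.88 and Oat (ornithine aminotransferase) at 3.88. Slc1a2 was at 4.59 (adjusted p = 0.00393) but did not pass with edgeR (0.0768). Wnt genes were higher in 8 of 17 cases and lower in 1 (10, 0.00112, adjusted p = 0.752 with an estimated correlation), among them Notum (2.53), Apcdd1 (3.20) and Zfp703 (0.84). Axin2 (0.62, 0.255) and Lgr5 (-0.05, 0.942) did not pass. Fatty acid oxidation genes were higher in 15 of 19 cases (19, 1.8e-12, adjusted p = 0.427 with an estimated correlation), such as Decr1 (1.20) and Hadha (0.75). Oncofetal genes were lower in 6 of 18 cases (7, 0.00926, adjusted p = 0.752 with an estimated correlation), with Peg3 at -4.35 and Grb10 at -3.39. Of YAP/TEAD targets 5 of 23 were lower and 1 higher (8, 0.0496, adjusted p = 0.752 with an estimated correlation), with Ctgf at -2.59 and Ankrd1 at -3.08 but the ecto-nucleotidase Nt5e at 4.21. Ribosomal protein genes were lower in 17 of 77 cases (17, 3.9e-08), cell cycle genes in 5 of 25 (0.00621), and female-biased genes higher in 6 of 16 (8, 5.46e-05), bile acid genes in 6 of 17 (9, 0.000429) and antigen presentation genes in 4 of 14 (0.00717), each with an adjusted p = 0.752 with an estimated correlation. Cholangiocyte and progenitor genes were lower in 5 of 15 cases and higher in 1 (7, 0.0523, not called), with Sox4 at -2.86 and Onecut2 at 1.93. Within the second set 11 of 20 pericentral genes were higher (camera 2.77e-07), 6 of 17 Wnt genes higher (0.000977), 11 of 19 fatty acid oxidation genes higher (2.16e-11), 3 of 18 oncofetal genes lower (0.0272) and 3 of 23 YAP/TEAD genes lower with 1 higher (0.144). With an estimated correlation the first 3 had an adjusted p = 0.642 there and the oncofetal list an adjusted p = 0.747. Of 92 called genes named by the rule 60 passed again within the set.

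In all 1150 genes were higher and 1240 lower in S33Y than in WT (limma), 1377 were called within the set, 637 in a fit of only the 2 groups, and 3844 without K335I 3, S33Y 1 and S33Y 2. The fit behind this last count keeps only the S33Y tumours nearest to normal liver. In the fit of only the 2 groups Ctnnb1 (adjusted p = 0.0816), Cyp1a2 (0.0543), Oat (0.0574), Slc1a2 (0.116), Notum (0.0548), Apcdd1 (0.0740) and Ankrd1 (0.0752) no longer passed. With no scale factor the share of higher genes went from 48.1% to 35.6% (median shift -0.12). The authors' deposited table lists 1893 genes for this pair.

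S33A tumours, of the other sequencing set than WT, showed more markers of non-tumour cells. Kupffer cell genes Clec4f (log2 fold change 5.07, 126 ± 69.7 against 5.68 CPM), Cd5l (4.60) and Vsig4 (3.54), the matrix proteoglycans Dcn (2.55) and Lum (2.04) and the sinusoidal endothelial genes Clec4g (3.54) and Dnase1l3 (2.54) were higher. Stellate cell and fibroblast markers were higher in 8 of 15 cases (12 over the list alone, camera 1.56e-06), antigen presentation genes in 8 of 14 (13, 1.56e-06), endothelial markers in 8 of 14 (8, 1.15e-05), macrophage and Kupffer cell markers in 5 of 16 with 1 lower (10, 0.000216) and lymphocyte markers in 5 of 10 (6, 0.000121), with adjusted p from 0.563 to 0.635 with an estimated correlation. Wnt genes were higher in 7 of 17 cases (7, 0.00259, adjusted p = 0.759 with an estimated correlation), with the Wnt inhibitors Apcdd1 (3.82) and Nkd1 (2.93, SE 0.72, adjusted p = 0.00578, 120 ± 47.6 against 23.5 ± 22.6 CPM), and pericentral genes in 3 of 20 (3, 0.0052, 0.759). Glul was at 2.23 (0.0107), but 0.0587 without WT 3. H19 was lower (-5.12, SE 1.42, 0.0125), as were Cr2 (-3.86), Bex1 (-3.86) and Ctnnb1 (-2.27, 7.38e-06), while Yap1 did not pass (0.06, 0.948). Higher by the most were Mup10 (6.64) and the lung and liver monooxygenase gene Cyp2f2 (6.05). Oncofetal genes were lower in 4 of 18 cases (4, 0.235). There were 983 higher and 1375 lower genes (limma), and the share of higher ones went from 41.7% to 51.9% with RLE factors and to 74.9% with no scale factor (median shift 0.13). The groups lie in different sequencing sets, so there is no value within a set for this pair.

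S45A and Del90 tumours differed from WT in some of the same lists, again across the sequencing sets. In S45A, H19 was at 11.5 against 2856 CPM (log2 fold change -6.45, SE 1.41, adjusted p = 0.00251), Igf2 at 2.74 (1.22 without S45A 4) against 1309 CPM (-6.02, SE 1.6, 0.0106) and Bex1 at -3.89, and Hist1h2ao (5.79), Clec4f (4.87), Nt5e (2.51) and Lum (1.78) were higher. With a term for the number series of the sample identifiers H19 (0.140), Igf2 (0.261), Bex1 (0.156), Nt5e (0.165), Clec4f (0.0980) and Lum (0.164) no longer passed, nor did Nt5e with edgeR (0.0541). All S45A identifiers lie below all WT identifiers, and only Del90 and S33A hold both low and high ones. The series term thus overlaps this contrast, and a lost call does not show that a gene follows the series. Stellate cell and fibroblast markers were higher in 5 of 15 cases (7 over the list alone, camera 0.000237, adjusted p = 0.905 with an estimated correlation), endothelial markers in 5 of 14 (6, 0.00726, 0.905), oncofetal genes lower in 5 of 18 (5, 0.341) and Wnt genes higher in 1 of 17. In Del90, the matrix genes Dcn (2.63) and Lum (2.40), the RNA-binding protein Rbms3 (1.53) and Hist1h2ao (5.90) were higher, and the kinase gene Styk1 (-3.31) and Cr2 (-2.99) lower. Stellate cell and fibroblast markers were higher in 5 of 15 cases (8, 3.1e-05, adjusted p = 0.848 with an estimated correlation), endothelial markers in 5 of 14 (6, 0.000393, 0.848) and pericentral genes in 3 of 20 (5, 0.00894, 0.848). Ctnnb1 was lower in both (-1.54, 0.000777 and -2.04, 7.59e-05), and Yap1 passed in neither (0.02, 0.984 and -0.04, 0.964). Hist1h2ao was at most 0.684 CPM in every tumour of the second set, so its rises here cannot be told apart from a set difference.

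For S45A 724 genes were higher and 1385 lower than in WT, and for Del90 476 and 865 (limma). Shares of higher genes went from 34.3% to 65.3% for S45A and from 35.5% to 84.5% for Del90 with no scale factor (median shift 0.13 for Del90), and to 46.5% for Del90 with RLE factors. S45A counts were 1062 without S45A 1, 1324 without WT 3 and 1382 without WT 4. Del90 counts were 425 without Del90 4, 582 without WT 4, 593 without WT 3, 690 without Del90 5 and 884 without Del90 2.

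Del20-32 tumours had 519 genes higher and 870 lower than WT tumours across the sets (limma), but 7 in a fit of only these 2 groups. H19 was at 17 against 2856 CPM (log2 fold change -6.75, SE 1.42, adjusted p = 0.0033), Bex1 at -3.90 and Grb10 at -2.78, while Tbx3 was at 181 ± 47.1 against 69.7 ± 47.5 CPM (1.58) and the hepcidin gene Hamp2 at 50.1 against 1.06 CPM (4.05). None of these, nor Ctnnb1 (-1.29, 0.00615), passed in the fit of 2 groups (H19 0.106, Bex1 0.0948, Grb10 0.116, Tbx3 0.135, Hamp2 0.0948, Ctnnb1 0.166), nor did H19 (0.120), Bex1 (0.159) and Grb10 (0.0622) with a term for the identifier series. All Del20-32 identifiers also lie below all WT identifiers, so that term overlaps this contrast too. Yap1 did not pass (-0.03, 0.979). Oncofetal genes were lower in 4 of 18 cases (5 over the list alone, camera 0.148), Wnt genes higher in 2 of 17 and lower in 1 (4, 0.582), and cell cycle genes lower in 4 of 25 (4, 0.0208, adjusted p = 0.999 with an estimated correlation). The count was 445 without Del20-32 5, 576 without WT 4, 724 without Del20-32 1 and 795 without WT 3, and the share of higher genes went from 37.4% to 60.0% with no scale factor.

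Del36-53, K335I and N387K tumours, of one sequencing set with WT, had few single genes called against WT. There were 2 higher and 5 lower for Del36-53, 3 and 6 for K335I and 3 and 5 for N387K (limma), and none within that set. At an unadjusted limma p under 0.05 were 1615, 2532 and 1583 of 14129 genes in that order. The few calls thus do not show that these tumours are alike. Ctnnb1 was lower in Del36-53 (log2 fold change -1.70, adjusted p = 0.0118, but 0.0582 without WT 4, 0.701 in a fit of the 2 groups and 0.147 within the set). In K335I it was at -1.69 (0.00759), but its call ended without 3 libraries (0.0697 without WT 3), in a fit of the 2 groups (0.368) and within the set (0.243). In N387K it did not pass (-0.79, 0.279), nor did Yap1 in any of the 3 (0.06, 0.982 for Del36-53, -1.26, 0.170 for K335I and -0.57, 0.685 for N387K). The extracellular signal Gdf10 was higher in N387K (2.57, 0.036, 10.4 against 1.02 CPM) but not in 8 of 10 fits without a library (0.115 without N387K 1), within the set (0.351), in a fit of the 2 groups (0.148) or with edgeR (0.0598). As lists, stellate cell and fibroblast markers lay higher in Del36-53 (10 of 15 over the list alone, camera 5.39e-09, adjusted p = 0.252 with an estimated correlation) and N387K (9, 2.53e-12, 0.171), and in K335I cell cycle genes lay lower (8 of 25, 1.39e-06, 0.627) and male-biased genes higher (8 of 14, 0.000103, 0.627). K335I 3 lay 73.7% of the way from the mean tumour to the mean normal liver, and without it camera gave 0.000794 and 0.0146 for these K335I lists, with an adjusted p = 0.768 with an estimated correlation for each. Wnt genes lay lower in N387K with none called singly (0.0119, 0.614). DESeq2 called 293, 507 and 231 genes, and the authors' deposited table lists 256, 298 and 184.

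Single libraries set these small counts. For Del36-53 they were 2 without WT 2 or WT 4, 4 without Del36-53 1, and 11, 12, 12, 13 and 18 without Del36-53 3, Del36-53 2, WT 1, Del36-53 5 and Del36-53 4. For K335I they were 1 without WT 2, WT 3 or WT 4, 2 without K335I 3, K335I 4 or K335I 5, 4 without K335I 2, and 34 and 38 without WT 1 and K335I 1. For N387K they were 0 without N387K 2, N387K 4 or N387K 5, 1 without WT 4 or WT 5, 2 without N387K 1 or WT 2 and 3 without WT 3. Shares of higher genes went from 28.6% to 50% (Del36-53) and from 33.3% to 0% (K335I) with no scale factor.

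**Figure D4:**
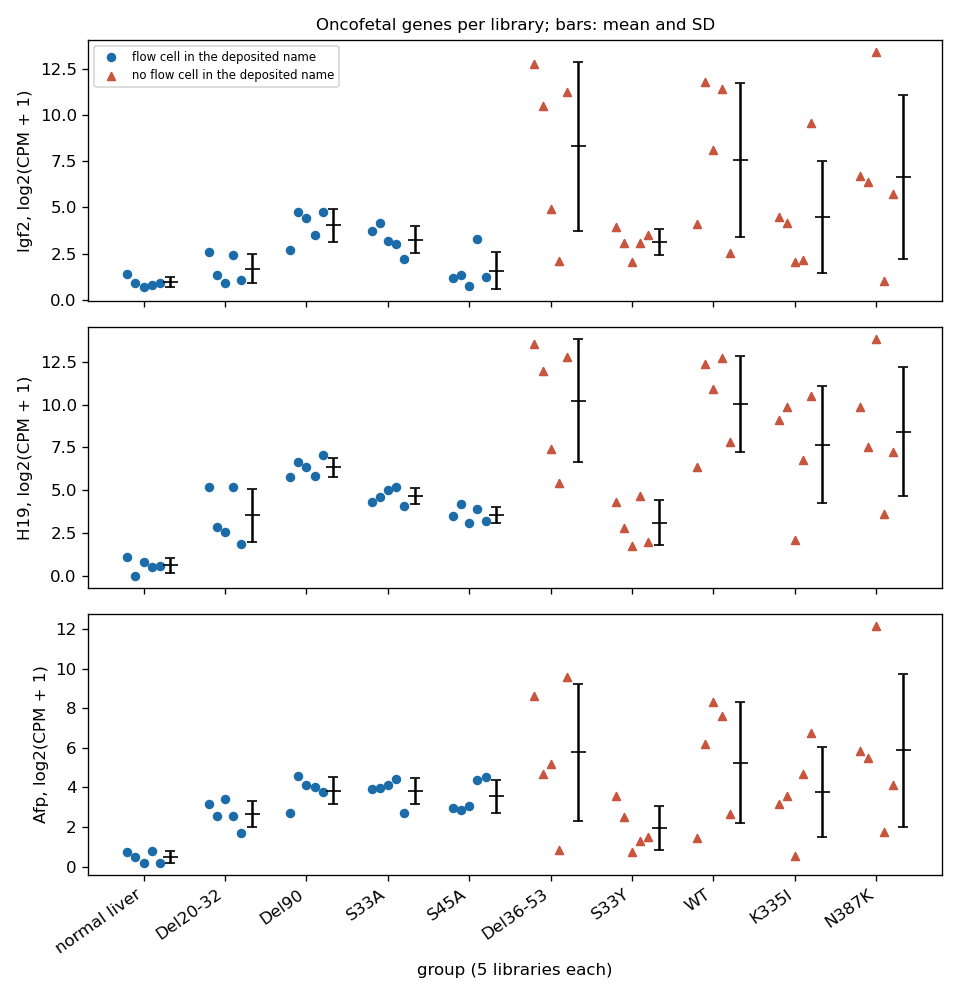
Igf2, H19 and Afp in each library, as log2(CPM + 1), with 5 points per group and the mean and SD as a bar beside them (blue circles, flow cell named; red triangles, none named). H19 lies over 100 CPM in 16 of the 25 libraries with no flow cell named, none of them S33Y, and in 1 of the 20 tumours with one named.

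Igf2, H19 and Afp spread widely within groups of the second set. Igf2 averaged 2264 ± 4930 CPM in N387K, 2169 ± 2838 in Del36-53, 1309 ± 1683 in WT and 161 ± 336 in K335I, against 8.52 ± 4.12 in S33Y and 2.6 ± 2.0 to 17.6 ± 9.28 in the tumours of the first set. Afp averaged 945 ± 2047 CPM in N387K, 241 ± 329 in Del36-53, 119 ± 137 in WT and 30.5 ± 44.1 in K335I, against 3.95 ± 4.20 in S33Y. The SD exceeds the mean in each of these 4 groups. Single libraries set 2 of them: without N387K 3 the N387K means were 59.5 ± 44.0 CPM of Igf2 and 29.5 ± 24.5 of Afp (n = 4), and without K335I 5 the K335I means were 11.3 ± 9.43 and 11.1 ± 10.3 CPM (n = 4), with Igf2 then within the range of the group means of the first set. H19 in N387K went from 3184 ± 6423 CPM to 316 ± 410 CPM (n = 4) without N387K 3.

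Tumours with K335I or N387K held less of several Wnt and pericentral transcripts than the 6 N-terminal mutants pooled, but the 5 genes named first did not pass against Del36-53 alone (limma). The Wnt inhibitor Nkd1 was at 6.26 ± 3.36 (n = 10) against 68.8 ± 46.6 CPM (n = 30, log2 fold change -2.95, SE 0.41, limma adjusted p = 2.15e-05), Glul at 621 ± 453 against 3769 ± 3834 CPM (-2.26, SE 0.35, 9.23e-05), Slc1a2 at 52.7 ± 92.8 against 677 ± 874 CPM (-4.06, SE 0.64, 0.000112, with a mean of 24.4 ± 26.7 CPM, n = 9, without K335I 3) and Tbx3 at 69.5 against 156 CPM (-0.98, 0.000331). Within the second sequencing set, against Del36-53 and S33Y, they were at -2.61 (0.0318), -2.47 (0.00999), -4.23 (0.0467) and -0.91 (0.0487). Notum was at -1.96 (0.000145), and at -1.71 (0.0750) within the set. Taken singly after these values were seen, the 2 groups of that set parted. Against S33Y the 5 genes were at -3.79, -4.11, -6.71, -2.23 and -3.10 (adjusted p from 1.51e-05 to 0.00149 within the set). Against Del36-53 they were at -1.44, -0.83, -1.75, 0.42 and -0.32 (0.566 to 0.875). Del36-53 tumours held 30.6 ± 30.0 CPM of Nkd1, 1292 ± 960 of Glul, 143 ± 147 of Slc1a2, 49.7 ± 9.37 of Tbx3 and 22.4 ± 20.2 of Notum. Lgr5 and Axin2 were at 0.89 (0.566) and 0.03 (0.985) against Del36-53. Thyroglobulin (Tg) was higher, 21.9 ± 25.1 against 0.447 CPM (2.96, SE 0.38, 3.06e-06, and 3.0, 0.0191 within the set, where it was at 2.88, 0.319 against Del36-53 alone). Further large differences were Hist1h2ao (-3.69, but at most 0.684 CPM in every tumour of the second set), Cyp2a5 (-2.75, but 0.281 within the set) and Ntrk2 (2.25, but 0.212 within the set). Ctnnb1 (0.45, adjusted p = 0.0929) and Yap1 (-0.80, 0.0615) did not pass, though with DESeq2 both did (0.049 and 0.036), as did Ctnnb1 without K335I 3, S33Y 1 and S33Y 2 (0.0209).

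Of the Wnt list 8 of 17 genes were lower in K335I and N387K than in the N-terminal mutants and none higher (9 over the list alone, camera 3.09e-09, adjusted p = 0.358 with an estimated correlation), and within the set 2 were lower (3.53e-07, adjusted p = 0.567 with an estimated correlation). Pericentral genes were lower in 2 of 20 cases (5, 0.000187, 0.74 with an estimated correlation, and 3 within the set, 0.0019, 0.692). Oncofetal genes were higher in 5 of 18 cases (6, 0.000126, 0.53 with an estimated correlation, and none within the set, 0.0019, 0.627). The 547 higher and 383 lower genes became 597 without N387K 2, 598 without K335I 4, 607 without N387K 4 and 83 within the second set, where 7 of 31 called genes named by the rule passed again. Of the 28 ways to part these 8 groups into 2 and 6, 8 called at least as many genes. With no scale factor the share of higher genes went from 58.8% to 21%.

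N-terminal deletions and N-terminal substitutions differed in 20 genes higher and 49 lower in the deletions (limma), and the 2 sequencing sets gave different values. Sox9 was at 69.5 ± 42.5 CPM in the deletions and 31.5 ± 24.1 in the substitutions (n = 15 each, log2 fold change 1.55, SE 0.28, adjusted p = 0.00267), but at 0.00 within the first set (Del20-32 and Del90 against S33A and S45A) and 4.48 within the second (Del36-53 against S33Y). Pkd2, a cilium channel, was at 1.17 (0.03 and 3.28 within the sets), Nt5e at -1.73 (-0.47 and -4.12), Adra1d at -1.59 (-0.79 and -3.59) and Aldh1a1 at -0.61 (-0.28 and -1.42). None of these 5 passed within the first set, and Nt5e did not with edgeR (0.0607). Glul was at -1.46 (0.0402) and did not pass in 19 of 30 fits without a library (0.0889 without Del90 1), with edgeR (0.106), with no filter (0.0793), with no scale factor (0.0530) or within the first set (-0.62, 0.44). Tbx3 was at -0.76 (0.021), at 0.12 within the first set, and did not pass without Del90 1 (0.0523) or with no scale factor (0.0530). Ctnnb1 (0.03, 0.962) and Yap1 (0.23, 0.767) did not pass. Pericentral genes were lower in 2 of 20 cases (7 over the list alone, camera 1.46e-11, adjusted p = 0.113 with an estimated correlation) and Wnt genes in 2 of 17 (7, 1.45e-08, 0.271). Within the first set no gene was called and within the second 1219. The count was 32 without Del90 1, 37 without Del20-32 4, Del36-53 5 or S33A 4, 38 without S45A 1, 41 without Del36-53 1 or S33A 2, 45 without S33Y 2 or S33Y 4 and 185 without Del36-53 2.

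S33Y and S33A change the same serine, a phosphorylation site, and their tumours differed widely, across the sequencing sets. S33Y 3, 4 and 5 lay nearer to normal liver (22.8 to 42.2% of the way from the mean tumour) than any S33A tumour (at most 17.1%). Sox9 was at 3.68 ± 1.88 in S33Y against 41 CPM in S33A (log2 fold change -3.28), the secreted phosphoprotein Spp1 at 22.3 against 300 CPM (-3.83), Ankrd1 at -3.22 and Ctgf at -2.64, while Cyp2c37 was at 202 against 19.9 CPM (2.91, SE 0.59, adjusted p = 0.000651), Tbx3 at 1.25, Aldh1a1 at 1.07 and Hadha at 0.71. Ctnnb1 was higher in S33Y (0.97, 0.0167), but 0.0740 without S33Y 3 and 0.125 with no scale factor. Yap1 did not pass (-0.85, 0.186), and passed without K335I 3, S33Y 1 and S33Y 2 (-1.44, 0.01), a fit that keeps only S33Y 3, 4 and 5. Cholangiocyte and progenitor genes were lower in 12 of 15 cases and higher in 1 (13 over the list alone, camera 0.000268), YAP/TEAD targets lower in 10 of 23 and higher in 2 (13, 0.000902) and fatty acid oxidation genes higher in 13 of 19 (19, 1.63e-07), each with an adjusted p = 0.667 with an estimated correlation. Macrophage and Kupffer cell markers were lower in 7 of 16 cases (9, 0.000902), lymphocyte markers in 6 of 10 (7, 0.000902), both again at 0.667, and pericentral genes higher in 5 of 20 (5, 0.0102, adjusted p = 0.709 with an estimated correlation). In all 1712 genes were higher and 1658 lower (limma), 1847 were called without S33Y 3, and the share of higher genes went from 50.8% to 15.9% with no scale factor (median shift -0.26). The authors' deposited table lists 2029.

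N387K and K335I tumours, of one sequencing set, did not differ in any gene by limma, with 820 genes at an unadjusted p under 0.05, 4 by DESeq2, 0 by edgeR and 0 in the authors' deposited table. Ctnnb1 was at 0.91 on the log2 scale (adjusted p = 0.782) and Yap1 at 0.69 (0.786). As lists, respiratory chain genes (camera 1.45e-09), pericentral genes (3.41e-07) and mature hepatocyte genes (8.6e-07) lay lower in N387K and cell cycle genes higher (8.6e-07), each with an adjusted p = 0.655 with an estimated correlation. K335I 3 lay 73.7% of the way from the mean tumour to the mean normal liver and apart from the other K335I libraries in Glul (1830 CPM) and Slc1a2 (307 CPM). Without it camera gave 0.000764, 2.66e-05, 0.00231 and 0.0104 for these 4 lists, each with an adjusted p = 0.809 with an estimated correlation.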

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

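Of the tests in this part, those of a normal liver under a tumour label, of the S33Y sex labels and of other splits of the libraries were chosen after the result was seen, and the fits within 1 sequencing set and without K335I 3, S33Y 1 and S33Y 2 were added after seeing the data.

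The tumours of the sequencing set with a named flow cell (Del20-32, Del90, S33A and S45A) differ from the others (Del36-53, K335I, N387K, S33Y and WT) in 5007 genes, 2205 higher and 2802 lower. Of the 126 ways to part 9 groups into 4 and 5, this split ranked 1 by the number of genes called, ahead of 4132 for the next (Del36-53, N387K, S33Y and WT against the rest) and a median of 263, so the values a batch difference needs are there. A difference in depth is argued against, since 95.99% of the 5007 calls were made again after every library was thinned to the same depth. Hist1h2ao, the gene with the smallest p among the tumour groups, averaged 4.654 CPM in normal liver (1.32 to 7.29), which shares the first set. This lies between the tumours of the first set (10.7 to 146) and of the second (at most 0.684). Every library of the first set, normal livers included, lay above every tumour of the second, as a set difference would give. The normal livers also lay below every tumour of their own set, so whether a library or counting difference sets this gene in any tissue stays open. The β-catenin forms themselves differ between the sets, and this biological difference cannot be told apart from a batch because no group spans both.

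K335I 3 lies 73.74% of the way from the mean of the other tumours to the mean of normal liver, where the other K335I libraries lie at -6.757 to 10.81%. Its scale factor was 0.7379 (0.9485 to 1.022 in the others), its Glul 1830 CPM (410.5 to 742.5) and its Slc1a2 306.8 CPM (3.988 to 80.52). A normal liver under a tumour label is argued against: the median of 15 tumour genes that were under 1 CPM in every normal liver was 3.549 CPM, against at most 0.345 in any normal liver and 66.1 in the other K335I tumours, and Yap1 was at 282 CPM. Normal tissue mixed into the sample would give 1 share from all genes, but genes high in normal liver gave a median share of 54.5% (quartiles 26.9 and 79.4, 114 genes) and genes high in tumours 91.6% (84.6 and 96.4, 113 genes). These ranges do not overlap, but the difference of 37.13 points is smaller than both quartile ranges added together, the limit set before the test, so a mixed sample and a tumour closer to normal liver cannot be told apart.

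In S33Y, 2 libraries had sex genes in the range of the other sex. The library labelled S33Y 1 (female) had 0.312 CPM of Xist and 132 CPM over 4 Y-linked genes, and the library labelled S33Y 2 (male) had 610 and 0.119 CPM, where other females had at least 322 CPM of Xist and at most 0.475 CPM of Y-linked genes and other males at most 3.39 and at least 66.5 CPM. RNA of the other sex mixed in is argued against, since it would leave the RNA that each label calls for, and neither library kept more than 0.08817% of the mean level in correctly labelled libraries (Y-linked genes in the library labelled male, Xist in the one labelled female). An exchange of the 2 labels with each other, which needs exactly these 2 libraries out of place, may account for it. No biological explanation was tested, and both libraries belong to 1 group, so the group means do not depend on it.

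Other libraries stood apart from the other 4 of their group by Dixon's criterion, which chance meets in about 5% of groups (20 of 160 here). Total reads of N387K 4 were 33.99 M (21.36 to 24.93 in the others). S45A 3 lay at -11.5% on the scale towards normal liver (-0.839 to 2.398). Yap1 was at 5222 CPM in N387K 5 (1654 to 2484) and 5284 in S45A 1 (2767 to 3458), Lgr5 at 40.77 in S33A 5 (53.05 to 56.58), Glul at 3830 in WT 1 (221.8 to 902.4) and Slc1a2 at 540.5 in S45A 3 (224.7 to 278.8). Igf2 was at 761.3 CPM in K335I 5 (3.147 to 21.57), 11080 in N387K 3 (1.027 to 102.1), 1.638 in normal liver 1 (0.6334 to 0.9045) and 8.842 in S45A 4 (0.6681 to 1.55). H19 was at 14660 CPM in N387K 3 (11.26 to 920), and Afp at 107.7 in K335I 5 (0.4687 to 25.04) and 4606 in N387K 3 (2.415 to 55.99). Del20-32 4 had 787.1 CPM of Gpc3 (170.3 to 268.1) and 113.6 of Sox9 (29.07 to 51.93).

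The difference between the sexes itself differed between tumours and normal liver in 93 genes by limma's interaction test. Cyp2b13 (log2 difference 6.766, adjusted p = 0.000833), Sult2a2 (6.115, 0.00307) and Sult2a1 (6.047, 0.0174) lay higher and Mup8 (-6.523, 7.69e-07), Cyp2d9 (-5.767, 0.0168) and Hsd3b5 (-5.321, 0.0166) lower. Of 100 splits 22 gave as many genes, and the highest other gave 261. These splits shuffled sex within groups. Normal liver (2 males, 3 females) allows few arrangements, so a part of the splits keeps its real sexes and may give large counts. The test could thus hardly exclude chance, and chance is not excluded. Without normal liver 4, Cyp2d9 and Hsd3b5 were at an adjusted p of 0.321, Sult2a1 at 0.229 and Sult2a2 at 0.135, and of these 6 genes only Cyp2b13 and Mup8 passed in every fit without 1 library. On recovered reads neither passed, with adjusted p of 0.59 and 0.97 by DESeq2 and 0.540 and 0.722 by edgeR.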

How the results depend on the processing

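The edgeR fits, the pseudocount, the values with no scale factor, the exchange of sexes, the fits without 3 libraries, those within 1 set and the list tests without K335I 3 were chosen after the data were seen; the other alternatives were fixed before. Counts against normal liver moved by less than 1.5 times in every alternative run. The cause was not tested for the changes below, except that fits of 2 groups or of 1 sequencing set hold fewer libraries. No paired analysis was possible because replicate numbers follow accession order. Among values of named genes per comparison, 2216 kept direction and side of the threshold with DESeq2 and 65 no longer passed; those that no longer passed numbered 30 with RLE factors, 138 with edgeR, 150 with a sample identifier series term, 187 with no filter, 205 with no scale factor, 96 with no sex term, 179 in fits of 2 groups, 167 within 1 set where 943 kept theirs (any difference in the second set, deletions against substitutions in the first), 135 with the sets of these 2 comparisons exchanged where 17 did, 25 with the pseudocount 0.25 21 without genes over 1 percent of reads, 20 with the sexes exchanged and 45 without 3 libraries. Depth limits genes near 1 CPM.

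With DESeq2 the counts were 450 for the sexes in tumours, 2089, 293, 2022, 507 and 231 for Del20-32, Del36-53, Del90, K335I and N387K against WT, 218 for deletions against substitutions and 4 for N387K against K335I. Sult2a1 in Del36-53 against normal liver turned to 0.6794 and Yap1 in Del90 against WT to 0.04299. With edgeR the interaction of sex and tissue gave 31 and N387K against WT 3, and Sult2a1 turned to 0.7757, Yap1 in Del90 against WT to 0.0108 and in S45A against WT to -0.03099. RLE factors gave 3 for N387K against WT, with Yap1 at 0.003517 in Del20-32 and 0.007576 in Del90 against WT. With an estimated correlation 7 of 333 list calls held, and fry made 233. With the identifier series term any difference among tumours gave 3050, S45A against WT 1263 and K335I and N387K against N-terminal mutants 513, with Yap1 at 0.3119 in Del20-32 and 0.1702 in Del90 against WT and Ctnnb1 at -0.009659 in deletions against substitutions. With no filter the counts were 575 for the sexes in normal liver, 133 in tumours, 337 for their interaction, 3 for K335I against WT and 1 for N387K against K335I.

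With no scale factor Del20-32 against WT gave 867, Del36-53 4 and K335I 2. Dock5 turned to 0.02168 in the tumour average and 0.0858 in Del90 against normal liver, Aldh1a1 to 0.0659 in Del90 against normal liver, and Yap1 to -0.05867 between the sexes in normal liver, 0.02838 in Del20-32 and 0.09278 in Del90 against WT. With no sex term Yap1 turned to 0.0495 in Del20-32 and -0.01611 in S33A against WT. Within the second sequencing set Del36-53, K335I and N387K against WT gave 0 by limma, S33Y against WT 1377, K335I and N387K against N-terminal mutants 83, any difference 734 and deletions against substitutions 1219, with Ctnnb1 at -0.4159 in the last. Within the first set any difference gave 18 and deletions against substitutions 0, with Yap1 at -0.1272, Dcdc2a at -0.547 and Tbx3 at 0.1222 in the latter. In fits of 2 groups, Del20-32, Del36-53, Del90, K335I, N387K and S33Y against WT gave 7, 0, 889, 0, 0 and 637. With the sexes of S33Y 1 and 2 exchanged Del36-53 against WT gave 11 and N387K 5. Without K335I 3, S33Y 1 and S33Y 2 the counts were 404 for the sexes in tumours, 16 for Del36-53, 2 for K335I and 3844 for S33Y against WT and 272 for deletions against substitutions, with Ctnnb1 at 0.005027 between the sexes in tumours.

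Leaving out 1 library at a time, the counts ran from 7807 to 9449 for the tumour average and, against normal liver, 6723 to 7775 for Del20-32, 7512 to 8940 for Del36-53, 6428 to 7297 for Del90, 5274 to 7229 for K335I, 6868 to 7953 for N387K, 7143 to 8038 for S33A, 5534 to 6869 for S33Y, 6764 to 7560 for S45A and 7667 to 8554 for WT. They ran from 3997 to 5837 for any difference among tumours, 61 to 275 for the sexes in normal liver, 108 to 3.9e+02 in tumours and 15 to 110 for their interaction. Against WT they ran from 445 to 1890 for Del20-32, 2 to 18 for Del36-53, 425 to 1564 for Del90, 1 to 38 for K335I, 0 to 12 for N387K, 1614 to 2350 for S33A, 1667 to 3187 for S33Y and 1062 to 2268 for S45A. Deletions against substitutions ran from 32 to 185, K335I and N387K against N-terminal mutants from 597 to 1132, S33Y against S33A from 1847 to 3756 and N387K against K335I stayed at 0. The libraries behind the changes over 1.5 times stand in the report.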

Other observations

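In this part the tests of the correlations and of other splits of the libraries or groups were chosen after the results they concern had been seen; the list tests were fixed before the data were examined.

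Igf2 and Afp were high in some tumours of a group, and H19 in most tumours of the second sequencing set outside S33Y. Of the 25 tumours with no flow cell named, 9 had over 100 CPM of Igf2, 16 of H19 and 6 of Afp, none of them S33Y, and of the 20 other tumours 0, 1 and 0 did. Among the 9 groups H19 (adjusted p = 0.000111, limma) and Igf2 (0.00339) differed and Afp did not pass (0.116), and within the second set H19 passed (0.0409) and Igf2 did not (0.225). S33Y tumours also stood apart in their tissue markers and mitochondrial genes from S33A: 7 of 22 respiratory chain genes were higher (9 over the list alone, camera 0.000386, adjusted p = 0.709 with an estimated correlation), 7 of 17 bile acid genes higher (8, 0.000902, adjusted p = 0.698 with an estimated correlation), 7 of 15 epithelial-mesenchymal genes lower with 1 higher (10, 0.0111) and 5 of 15 stellate cell and fibroblast markers lower (9, 0.000268), the last 2 lists with an adjusted p = 0.667 with an estimated correlation. These lists compare groups of different sequencing sets.

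In tumours, cholesterol synthesis genes lay higher in males with 1 of 18 called (9 over the list alone, camera 9.94e-09, adjusted p = 0.544 with an estimated correlation), and bile acid genes with 2 of 17 called (7, 1.35e-07, 0.388). In normal liver, antigen presentation genes lay lower in males with none called singly (11 over the list alone, camera 8.69e-10, adjusted p = 0.0607 with an estimated correlation).

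One hypothesis is that Igf2 and H19, neighbours in an imprinted region, rise together across tumours. Across the 25 tumours of the second set rho was 0.8938 and r 0.8895 (permutation p = 1e-05 for each, the smallest that the permutations can give, with 1.71e-05 and 2.4e-05 for r and rho after adjustment over 12 relations), and r was 0.8603 without the 2 libraries farthest from the median of Igf2. These values include differences between the groups. Around the group means r was 0.9005 and rho 0.9023 in the second set (permutation p = 1e-05 for each) and 0.6356 (p = 0.00242, adjusted 0.00323) and 0.7699 (p = 0.00012, adjusted 0.000206) in the first, where they were 0.8484 and 0.8241 before, and without 2 libraries r was 0.861 and 0.6255. Igf2 and Afp around the group means gave r = 0.8638 and rho = 0.8438 in the second set, and 0.5607 (p = 0.0101, adjusted 0.0111) and 0.4872 (p = 0.0315, adjusted 0.0344) in the first, with r at 0.7974 and 0.4697 without 2 libraries. A shared control of the region in these tumours may account for this, as may a fetal-like cell state of some tumours, and the values do not part the explanations.

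Another hypothesis is that tumours of 1 group differ in how much of both plasmids they express. Around the group means Ctnnb1 and Yap1 gave r = 0.6249 over the 45 tumours (permutation p = 1e-05, adjusted 1.71e-05) and rho = 0.5385 (p = 0.00014, adjusted 0.00021), and r = 0.5348 without the 2 libraries farthest from the median. Within the second set r was 0.725 (p = 3e-05) and rho 0.6192 (p = 0.00117), but within the first r was 0.2897 (p = 0.215) and rho 0.3684 (p = 0.112), so the relation did not pass there. A varying share of tumour cells in the samples may give the same relation. Glul and Slc1a2, around the group means, gave r = 0.7808 and rho = 0.7619, and r = 0.76 without 2 libraries.

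Chance in how single libraries fall into groups can be excluded for most counts of called genes by drawing up to 100 other splits of the same libraries, which break up the groups and sequencing sets. For the tumour average against normal liver 1 of 100 splits, the real one, reached 9257 genes and the highest other gave 75. This was also so for any difference among tumours (4792, highest other 3), K335I and N387K against N-terminal mutants (930 and 4) and the sexes in tumours (228 and 121). In fits of each tumour group and normal liver the real split was again the only 1 as large, with 6687 and 10 for Del20-32, 7167 and 0 for Del36-53, 7906 and 12 for Del90, 5904 and 3658 for K335I, 7773 and 2 for N387K, 8835 and 1 for S33A, 5688 and 0 for S33Y, 8086 and 27 for S45A and 7627 and 6 for WT. Against WT it was so for Del90 (889 and 353), S33A (2391 and 5), S33Y (637 and 432) and S45A (1747 and 3), and for S33Y against S33A (2653 and 1170). For Del20-32 against WT 2 splits reached 7 genes and the highest other gave 11. For deletions against substitutions 3 splits reached 69 and the highest other gave 600, several times the real count, which points to a structure of the samples. Splits of whole groups keep that structure. For K335I and N387K against N-terminal mutants 8 of the 28 splits of whole groups reached 930 and the highest other, K335I and S33Y against the rest, gave 3780, so chance in which groups are pooled is not excluded for this count. For deletions against substitutions there are 10 splits of whole groups, too few for a share under 0.05, with 69 genes in the real split and 2003 in the highest other. Fits of 2 groups called 0 genes by limma for Del36-53, K335I and N387K against WT and N387K against K335I, a count that 100 of 100 splits reach by construction, so the splits say nothing about chance for these 4 pairs. Their highest others were 10, 9, 5 and 2.2e+03, the last again a sign of structure among the K335I and N387K libraries. The sexes in normal liver (2 males) were not tested in this way.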
